A study of Mus musculus with 6 samples.

How the data were processed

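The libraries were made from mouse embryonic stem (ES) cells of the D6AdP line, in which both copies of Ddx6 carry an auxin-inducible degron and mCherry, 1 copy of Dcp1a carries EGFP, and a transgene supplies the plant F-box protein OsTIR1, which recruits degron-tagged proteins to the proteasome when an auxin is present. Per the labels' protocols, cells were plated on fibroblast feeder cells and kept with leukemia inhibiting factor, the MEK inhibitor PD0325901 and the GSK3 inhibitor CHIR99021. The auxin analog 5-Ph-IAA was added at 500 nM for 0, 3 or 6 h. RNA with an integrity number over 8.0 was used, and polyA RNA from 500 to 1000 ng of total RNA was made into stranded, single-end libraries. There were 2 libraries for each of the 3 times and 6 in all.

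The deposited file is a table of raw counts, whole numbers of reads per Ensembl gene for each library, with 55487 genes. The submitters' processing notes name fastp 0.22.0, HISAT2 2.2.1 and featureCounts 2.0.3 and the build GRCm38 (mm10). The annotation release, the strand setting and the treatment of reads with several matches are not given in the sources used here. Counts of near-identical gene copies, and of genes whose exons overlap another gene, are therefore uncertain. Gene names, positions, coding sequences and 3' UTRs were taken from GENCODE M21, which is on the same build. A symbol was found for 55141 IDs, and the remaining IDs held 0.0231% of the counts.

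Everything below was computed here from those counts with R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The totals ran from 16357142 to 21846959 counts per library, so 3 counts stood for 0.137 to 0.183 CPM. Genes were kept by filterByExpr with its default minimum of 10 counts, which left 15748 genes and 99.9% of the counts. Libraries were scaled with TMM factors, and edgeR's quasi-likelihood test was run in 1 fit of all 6 libraries with 3 group means, 3 residual degrees of freedom, 13.7 prior degrees of freedom and no covariate. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, two-sided. The standard error (SE) of a log2 fold change is its size divided by the square root of F. CPM values are TMM-scaled. The labels do not say that the libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

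Before the data were examined, 40 gene lists, the tests, the alternatives and the rule for naming genes were fixed. Each list was tested against the other genes with limma's camera on voom values, with a preset correlation of 0.01 and adjustment over the 40 lists, and again with an estimated correlation. Member counts are given over all genes tested and adjusted over the list alone. Of 778 list entries 702 were tested. The rule named Ddx6 and Dcp1a, then for each comparison with 0 h the 8 largest rises and 8 largest falls among changed genes with an average log2 CPM of at least 1 and no overlap in CPM between the groups. For 6 h against 3 h it took 5 of each. Predicted genes (Gm numbers, Rik names, pseudogene and AC, AL or BC clone names) were left out of naming. For each list it took up to 3 changed members with the smallest adjusted p, or, where none changed, allowed the member with the highest CPM. Genes named outside this rule are marked as chosen after their values were seen. Some genes that the rule named are not reported here.

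Seed sites were matches to AGCACTT, the 7mer that pairs with the seed AAGUGCU of the miR-290 and miR-302 families, in the longest annotated 3' UTR of at least 50 nt. They were compared with the other 7mers of the same base composition that occur in at least 100 genes. GC content was related to fold changes by Spearman's rho across genes, which are not independent replicates. Because both treated times were compared with the same 0 h libraries, 20 simulated data sets with unchanged groups gave the chance level of their correlation.

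Replicates were checked for duplicate libraries with a chi-square test of their counts. The alternatives were other size factors, no filter, a CPM minimum, DESeq2, limma voom, the legacy edgeR test, a replicate block, a feeder-marker covariate, fits of 4 libraries and leaving out each library. Added after seeing the data were library sizes without scaling factors, a GC offset, thinning to equal depth, leaving out 5 genes that collect ribosomal RNA reads together with Ldb1, list tests for 6 h against 3 h, 10000 random lists per fixed list drawn from the same bins of mean expression, and the overlap of p-ranked lists in the simulated data sets.

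The tests were tried on simulated counts in which 200 genes were changed. For 3 h against 0 h, with 15540 genes tested, 70% of genes with the smallest planted change, 92% of those changed 1.5-fold, 98% of those changed 2-fold and 100% of those changed 3-fold were called, with 12 false calls among 192. For 6 h against 0 h, with 15531 genes tested, the shares were 64%, 82%, 98% and 100%, with 12 false calls among 184. A list shifted by 0.3 on the log2 scale was recovered in both comparisons, with medians of 0.30 and 0.30 and no other list called. Genes were drawn independently there, whereas in the data the estimated correlation was 0.61 for the feeder fibroblast list at 3 h. The trial therefore cannot show how often camera overcalls lists whose members move together. The random lists matched on expression were also drawn gene by gene. Lists whose members move together can thus fall outside their range too easily. A planted shift of 0.05 in genes with a seed site was recovered as 0.05 over 13511 genes.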

Results

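RNA-seq of polyA RNA was done on mouse ES cells before and 3 and 6 h after addition of an auxin analog that acts on degron-tagged DDX6. DDX6 is an RNA helicase that represses translation, promotes decapping of mRNA and is needed for P-bodies, the cytoplasmic granules in which DCP1A also gathers. Each time had 2 libraries. The totals were 19405226 and 21846959 counts at 0 h, 21310286 and 21843536 at 3 h, and 16357142 and 18323611 at 6 h. Between 23140 and 23720 genes had at least 1 count. Replicates correlated at r = 0.997, 0.997 and 0.996 for log2 CPM at 0, 3 and 6 h, across genes, and every pair differed by more than sampling noise (chi-square per degree of freedom 4.56, 2.07 and 7.08). The first principal component held 43.1% of the variance and separated the 6 h libraries, at 25.5 and 22.9, from the other 4, at -13.7 to -10.5. The libraries used here held no untreated wells kept for 3 or 6 h and no treated ES cells without the degron. The comparisons therefore cover the analog, any handling of the medium, the hours in culture and the loss of DDX6 together.

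The mRNA of the tagged gene, Ddx6 (ENSMUSG00000032097, chromosome 9, 44604892 to 44640731, GRCm38), was not called changed at either time. It measured 259 ± 12.4 CPM at 0 h, 270 ± 1.98 at 3 h and 253 ± 7.87 at 6 h (SD, n = 2 each). Its log2 fold change was 0.06 ± 0.04 (SE) at 3 h (edgeR adjusted p = 0.602) and -0.03 ± 0.04 at 6 h (adjusted p = 0.581). The degron acts on the protein, so these values do not check the depletion. Dcp1a (ENSMUSG00000021962, chromosome 14, 30479535 to 30527063), which encodes a decapping cofactor, had a log2 fold change of -0.02 ± 0.04 at 3 h (adjusted p = 0.905). At 6 h Dcp1a was lower, from 88.9 ± 2.71 to 81.0 ± 0.473 CPM (log2 fold change -0.13 ± 0.04, adjusted p = 0.0346), a call that DESeq2 did not make.

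In the early comparison, 3 h against 0 h, few genes were called, and Trim25, Ppp1r10 and Spry4 had the smallest adjusted p. Spry4, a feedback inhibitor of ERK signalling (ENSMUSG00000024427, chromosome 18, 38586247 to 38601415), fell from 64.1 ± 3.09 to 45.0 ± 0.0863 CPM (log2 fold change -0.51 ± 0.05, adjusted p = 0.000546). Trim25, a ubiquitin ligase, fell by 0.34 on the log2 scale and Ppp1r10, a nuclear subunit of protein phosphatase 1, by 0.38 (adjusted p = 0.000546 for both). Dusp6, an ERK phosphatase, fell by 0.47 (adjusted p = 0.00642), a call that 4 of the 6 fits without a library made and DESeq2 did not (adjusted p = 0.0989). Icosl, a ligand for a T cell costimulatory receptor, fell by 0.64, Adamts1 by 0.35, Zfp65 by 0.34 and Tbc1d24 by 0.29. The largest rise was in Egln3, a prolyl hydroxylase that targets the hypoxia-inducible factors, at a log2 fold change of 0.46 ± 0.07 (adjusted p = 0.0205). Mxi1, a MYC antagonist, rose by 0.32, Elf3 by 0.31, Zranb1 by 0.28, Tex19.1 by 0.28, the pluripotency factor Klf4 by 0.28, Tnrc6a by 0.27 and Chka by 0.26. Tnrc6a encodes a GW182 protein of microRNA silencing. In all, edgeR called 22 of 15748 genes, 8 higher and 14 lower, and 1679 had an unadjusted p under 0.05. Only 1 of the 22, Icosl, had a fitted change of at least 1.5-fold. The count was 4 without replicate 1 of 3 h, 7 without its replicate 2, 12 without replicate 1 of 0 h, 249 without replicate 2 of 0 h, 89 without replicate 1 of 6 h and 88 without its replicate 2. It was 0 with no filter on low counts (1839 genes at an unadjusted p under 0.05), 12 with DESeq2, 35 without 5 genes that collect ribosomal RNA reads and Ldb1, 53 with the feeder-marker mean as a covariate and 74 with only the 4 libraries compared. Only Trim25, Ppp1r10 and Spry4 were called in all 6 fits that left out a library, and DESeq2 called 10 of the 22.

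Among the fixed lists at 3 h, FGF and ERK target genes were lower with a median log2 fold change of -0.16. Of its 17 members 2 fell, Spry4 and Dusp6, and 7 were lower adjusted over the list alone (camera adjusted p = 1.77e-09, and adjusted p = 0.461 with an estimated correlation). Markers of feeder fibroblasts were lower with a median of -0.14 over 29 genes (adjusted p = 2.49e-19, and adjusted p = 0.461 with an estimated correlation). None of them was called changed over all genes, and 20 were lower adjusted over the list alone. The most abundant, Fn1, measured 5383 CPM at 0 h and 5092 at 3 h (log2 fold change -0.08 ± 0.04, adjusted p = 0.456). The mean log2 CPM of that list was 8.90 and 8.80 in the 0 h libraries, 8.70 and 8.70 at 3 h, and 8.91 and 8.75 at 6 h. Lower medians with no member called over all genes were also found for immediate early genes (-0.07, adjusted p = 0.000978), mRNAs with AU-rich elements (-0.09, adjusted p = 0.000978), p53 targets (-0.05, adjusted p = 0.00196), cytosolic ribosomal proteins (-0.03, adjusted p = 0.00196), endoderm genes (-0.19, adjusted p = 0.0277) and Wnt target genes (-0.12, adjusted p = 0.0333). The endoderm medians lay near those of the feeder markers in each comparison. At 3 h, at 6 h and for 6 h against 3 h they were -0.19, -0.0083 and 0.16. The feeder medians were -0.14, -0.018 and 0.13. Whether feeder RNA contributed to the endoderm list was not tested. Higher medians, again with no member called, were found for CCR4-NOT and deadenylation factors (0.04, adjusted p = 0.00626) and G2 and M phase genes (0.02, adjusted p = 0.0360). With an estimated correlation the adjusted p = 0.461 for immediate early genes, mRNAs with AU-rich elements, p53 targets and endoderm genes, 0.723 for ribosomal proteins, 0.483 for Wnt targets, 0.559 for CCR4-NOT and 0.788 for G2 and M. Adjusted over the list alone, 4 immediate early genes, 7 mRNAs with AU-rich elements, 2 p53 targets and 6 Wnt targets were lower, 1 Wnt target and 1 CCR4-NOT gene were higher, and no ribosomal protein, endoderm or G2 and M gene was called. Thus 10 of the 40 lists passed with the preset correlation, 2 higher and 8 lower, and none with an estimated one (lowest unadjusted p = 0.0253). By fry, which asks whether a list's genes move on balance one way, none passed. The median, the mean and the test had the same sign in each of the 10, and not in 7 of the other lists. The medians of the CCR4-NOT and the G2 and M lists lay within the central 95% of 10000 random lists matched on expression (97.2% and 90.8% of these were below), and the other 8 lay outside. In the fits without a library 4 of the 10 passed every time. Endoderm, CCR4-NOT, Wnt and G2 and M lists did not pass without replicate 1 of 0 h (adjusted p = 0.0617, 0.0617, 0.221 and 0.822) or without replicate 2 of 3 h (0.0773, 0.202, 0.195 and 0.207). Immediate early genes did not pass without replicate 1 of 0 h (0.0617) and ribosomal proteins without its replicate 2 (0.219). The G2 and M median was -0.01 without replicate 1 of 0 h. The other 30 lists had camera adjusted p from 0.0530 to 0.999, and 5 of them lay outside their matched range, the mesoderm, aryl hydrocarbon receptor and LIF and STAT3 lists below and the glycolysis and hypoxia and the G1 and S lists above.

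At 6 h the changes were broad and mostly small. The largest falls were in Nr4a3, an immediate early nuclear receptor (log2 fold change -2.06 ± 0.18, adjusted p = 5.91e-07), the corepressor Ripply3 (-1.94 ± 0.26), Pudp (-1.71 ± 0.24), the receptor Gpr83 (-1.65 ± 0.16), Fgfbp1 (-1.37 ± 0.15), the deiodinase Dio2 (-1.36 ± 0.23), Aqp3 (-1.26 ± 0.05) and Fam189a2 (-1.21 ± 0.11). Aqp3, a channel for water and glycerol (chromosome 4, 41092722 to 41098183), went from 78.5 ± 1.49 to 32.8 ± 1.77 CPM. The largest rises were in Cdk5r2, an activator of the kinase CDK5 (1.66 ± 0.19), Egln3 (1.56 ± 0.07), the kinesin Kif26a (1.54 ± 0.21), Ankrd37 (1.30 ± 0.14), the non-coding RNA Platr11 (1.29 ± 0.20) and Otx2, a factor of the primed epiblast (1.26 ± 0.22, with a 6 h mean of 8.55 ± 3.47 CPM). Egln3 (ENSMUSG00000035105, chromosome 12, 54178981 to 54203860) went from 25.4 ± 1.11 CPM at 0 h to 34.9 ± 1.01 at 3 h and 74.8 ± 8.99 at 6 h. The rule also named CT010467.1 (1.46 ± 0.36) and Lars2 (1.32 ± 0.33), whose calls were lost with DESeq2 and which varied widely within a group. CT010467.1 measured 1384 and 4459 CPM in the 0 h libraries and 10913 and 5197 CPM in the 6 h libraries. Exons of Ankrd37 overlap a gene on the opposite strand over 26.4% of their length, and those of CT010467.1 over 73.9%. In all, 3515 genes were called, 1575 higher and 1940 lower, with a median change of 1.22-fold. Of these, 361 rose and 220 fell by at least 1.5-fold, and 132 and 88 by at least 2-fold.

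**Figure D1:**
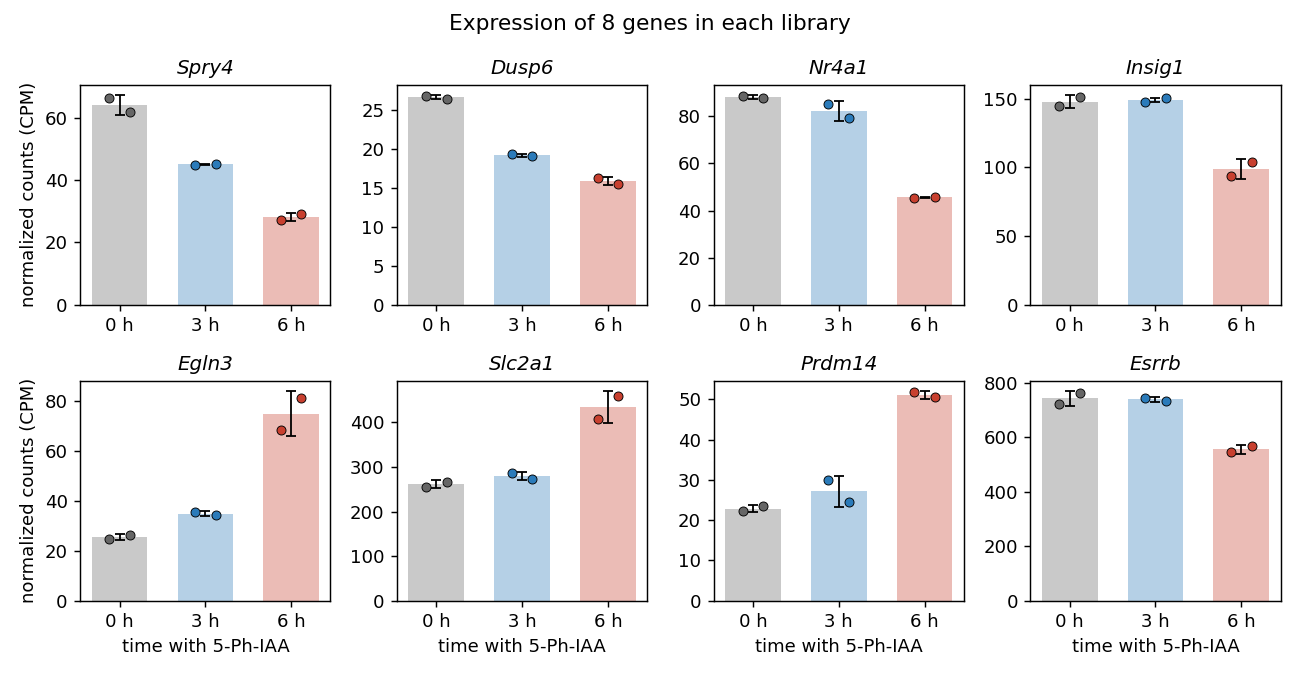
Normalized counts (CPM, vertical axis, starting at 0) of 8 genes against the time with 5-Ph-IAA. Points are the 2 libraries of each time, bars their mean and error lines the SD. Spry4, Dusp6, Nr4a1, Insig1 and Esrrb were lower at 6 h and Egln3, Slc2a1 and Prdm14 higher, and Spry4, Dusp6 and Egln3 had already changed at 3 h.

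At 6 h more members fell than rose in the lists of FGF and ERK targets, immediate early genes, mRNAs with AU-rich elements and LIF and STAT3 targets. Of 17 FGF and ERK target genes 11 fell and none rose, also adjusted over the list alone (median -0.32). Spry4 fell by 1.19 on the log2 scale, from 64.1 to 28.2 CPM, Il17rd by 0.64 and Spry2 by 0.42. The list passed with camera (adjusted p = 2.77e-08, and adjusted p = 0.362 with an estimated correlation). Of 29 immediate early genes 17 fell and none rose, over all genes and adjusted over the list alone (median -0.32, adjusted p = 2.77e-08, and adjusted p = 0.258 with an estimated correlation). Nr4a1 fell by 0.95 and Klf10 by 0.40 beside Nr4a3. Of 17 mRNAs with AU-rich elements 10 fell and 1 rose, against 11 and 1 adjusted over the list alone (median -0.29, adjusted p = 9.73e-07, and adjusted p = 0.212 with an estimated correlation). The kinase genes Pim3 and Pim1 fell by 0.69 and 0.48, and Ptgs2, the inducible cyclooxygenase, by 0.72. The 1 member that rose was Cxcl5 (0.43), which was named after its value was seen. Of 16 LIF and STAT3 target genes 9 fell and 1, Klf4, rose, against 10 and 1 adjusted over the list alone (median -0.34, adjusted p = 5.97e-07, and adjusted p = 0.212 with an estimated correlation). Pim3 is shared with the AU-rich list, Socs2 fell by 0.54 and Tfcp2l1 by 0.30.

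The pluripotency network changed in both directions. Of 20 naive pluripotency genes 13 fell and 4 rose, against 14 and 4 adjusted over the list alone (median -0.30, adjusted p = 1.60e-06, and adjusted p = 0.398 with an estimated correlation). Nr0b1 fell by 0.95, from 111 to 57.5 CPM, and Esrrb by 0.42. Prdm14 (chromosome 1, 13113457 to 13127163) rose from 22.8 ± 0.863 to 51.2 ± 0.911 CPM, a log2 fold change of 1.16 ± 0.08. The other 3 that rose were Klf4 (0.17), Tdgf1 (0.14) and Nanog (0.13), of which Nanog was named after its value was seen. Of 12 core pluripotency genes 4 fell, among them Lin28a (-0.31), Zfp281 (-0.25) and Sall4 (-0.24), and 1 rose, with the same counts adjusted over the list alone (median -0.07, adjusted p = 0.0133, and adjusted p = 0.302 with an estimated correlation). The 1 that rose was Sox2 (0.13), named after its value was seen. Genes of the primed state did not pass camera as a list (adjusted p = 0.338), with 5 of 14 higher and 3 lower, but passed fry as higher (fry adjusted p = 0.0316). Among them Sall2 rose by 0.84 and Lef1 by 0.62 beside Otx2, whereas Dusp6 fell by 0.74. Genes of the 2-cell-like state were lower (median -0.73, adjusted p = 0.0102, and adjusted p = 0.302 with an estimated correlation). Of its 13 tested members Zscan4b and Usp17la fell, from 0.610 and 1.07 CPM, and both belong to multicopy families whose reads cannot be assigned with certainty.

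Of 28 genes of glucose uptake, glycolysis and hypoxia 11 rose and none fell, against 16 higher and 1 lower adjusted over the list alone (median 0.11, adjusted p = 6.61e-07, adjusted p = 0.432 with an estimated correlation and 0.0705 by fry). Besides Egln3, the glucose transporter Slc2a1 rose from 261 to 434 CPM (log2 fold change 0.73 ± 0.05) and the lactate transporter Slc16a3 by 0.59. Of 24 cholesterol synthesis genes 12 fell and none rose, against 16 lower adjusted over the list alone (median -0.20, adjusted p = 3.36e-07, and adjusted p = 0.212 with an estimated correlation). The sterol sensor Insig1 fell by 0.58 and the demethylase Cyp51 by 0.47. Heat shock genes had 4 of 16 members higher, against 5 adjusted over the list alone, among them Hsph1 (0.26), Ahsa1 (0.23) and Hspa8 (0.19) (median 0.03, adjusted p = 0.0357, and adjusted p = 0.398 with an estimated correlation). Of 29 oxidative phosphorylation genes Ndufs4 (-0.23) and Cox7c (-0.21) fell, the same 2 adjusted over the list alone (median -0.07, adjusted p = 0.00884, and adjusted p = 0.398 with an estimated correlation).

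Lists of abundant genes were also compared with expression-matched genes, because across 13511 genes the change at 6 h was related to average log2 CPM at rho = -0.259 (0.0739 at 3 h). Of 50 cytosolic ribosomal protein genes 26 fell and none rose, against 35 lower adjusted over the list alone, with a median log2 fold change of -0.10 (adjusted p = 3.90e-12, and adjusted p = 0.398 with an estimated correlation). Rpl27 fell by 0.20, Rplp2 by 0.15 and Rps18 by 0.15, and pseudogene copies of this family could share their reads. Of 10000 random lists matched on expression, 1.58% had a median below that of the ribosomal protein list, and the central 95% of them ran from -0.09 to -0.04. Of 26 translation factors 6 fell and 1 rose, against 13 and 2 adjusted over the list alone (median -0.07, adjusted p = 0.000219, and adjusted p = 0.362 with an estimated correlation). The median of the translation list was within the range of matched lists, of which 32.5% were below it. Eif1 fell by 0.45 and Eif4ebp2 by 0.25, and Eif4g3 rose by 0.38. Of 26 G1 and S phase genes 17 fell, including the replication licensing genes Orc1 (-0.41) and Cdt1 (-0.33) and Uhrf1 (-0.23), and 1 rose, Ccne1 (0.18, named after its value was seen). The counts were 19 and 1 adjusted over the list alone (median -0.14, adjusted p = 2.53e-07, and adjusted p = 0.302 with an estimated correlation), and 0.07% of matched lists had a lower median than the G1 and S list. Of 28 G2 and M phase genes 4 rose, among them Cdc25b (0.46) and Kif23 (0.42), and 3 fell, among them Ccnb1 (-0.21), and the list did not pass (adjusted p = 0.585). Of 29 p53 targets 13 fell and 2 rose, against 15 and 2 adjusted over the list alone (median -0.12, adjusted p = 0.000313, and adjusted p = 0.212 with an estimated correlation). Aen fell by 0.39, Gtse1 by 0.37 and Trp53inp1 by 0.32.

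Lists of mRNA decay and microRNA pathway factors had median log2 fold changes from -0.15 to 0.02 at 6 h. Of 23 P-body and decapping factors 6 fell and 3 rose. The list did not pass camera (median -0.08, adjusted p = 0.176) but passed fry as lower (fry adjusted p = 0.0458). The endonuclease gene Zc3h12a fell by 0.50, Patl1 by 0.20 and the decapping enzyme gene Dcp2 by 0.18. Of 19 CCR4-NOT and deadenylation factors 6 fell and 2 rose, against 7 and 2 adjusted over the list alone (median -0.06, adjusted p = 0.0357, and adjusted p = 0.476 with an estimated correlation). Cnot8 fell by 0.45 and Btg1 by 0.38, and Cnot6l rose by 0.56. Of 14 nonsense-mediated decay factors 8 fell and none rose, over all genes and adjusted over the list alone (median -0.15, adjusted p = 0.000418, and adjusted p = 0.398 with an estimated correlation), with Smg5 at -0.34 and Casc3 at -0.19. Of 15 microRNA pathway genes 3 rose and 2 fell (adjusted p = 0.960), with Tnrc6b at 0.50, Lin28a at -0.31 and Dgcr8 at -0.25.

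The listed microRNA targets did not pass camera as a group, while fry passed them as lower (fry adjusted p = 0.0142). DDX6 binds the CCR4-NOT complex that microRNA-bound Argonaute recruits, and the miR-290 and miR-302 families are abundant in ES cells. Of 19 listed targets of these families 2 rose and 5 fell at 6 h (median -0.05, camera adjusted p = 0.254). Among those that fell were Lefty1 at -0.67, Lats2 at -0.38 and Wee1 at -0.23. Exons of Lats2 overlap another gene on the same strand over 42.4% of their length. Across 13511 genes with an annotated 3' UTR, the 2384 with a site for the shared seed (AGCACTT) had a median log2 fold change that was 0.0071 above that of the 11127 without at 6 h. Of the other 619 7mers of the same composition a share of 0.387 gave a difference at least as large. At 3 h the difference was also 0.0071, with a share of 0.185. By terciles of 3' UTR length the 6 h differences were 0.039, 0.029 and -0.00017 from the shortest to the longest, with a mean of 0.023 and shares of 0.0696, 0.0640 and 0.984. The 479 genes with an 8mer site differed by 0.0078. Its share of 0.350 was taken over the same 619 7mers and not over other 8mers, so the groups compared differ in size and site length.

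The remaining lists did not pass camera at 6 h, and the adjusted p-values of lists given here are from camera. Of 27 integrated stress response genes 6 rose and 12 fell (adjusted p = 0.127), with Chac1 at 1.16, Ddit4 at 0.37 and Slc7a5 at -0.28. Unfolded protein response genes had 4 of 18 higher (adjusted p = 0.140), with Herpud1 at 0.33, Pdia4 at 0.17 and Hspa5 at 0.14. Targets of the aryl hydrocarbon receptor, which some indoles activate, had 3 of 7 higher (adjusted p = 0.176), Ahrr at 0.58, Cyp1b1 at 0.43 and Nqo1 at 0.30. BMP pathway targets had 2 of 13 higher and 5 lower (adjusted p = 0.315), with Id2 at -0.89, Id1 at -0.51 and Smad7 at -0.18, and negative regulators of BMP signalling had 2 of 24 higher and 3 lower (adjusted p = 0.585), with Tob2 at -0.33 and Tob1 at 0.23. Nodal and activin targets had 1 of 10 higher and 3 lower (adjusted p = 0.585), Notch targets 5 of 11 lower (adjusted p = 0.217), with Notch1 at -0.23, and Wnt targets 3 of 18 higher and 3 lower (adjusted p = 0.673), with Axin2 at -0.37 and Cdx1 at -0.35. Markers of mesoderm and primitive streak (adjusted p = 0.987), endoderm (0.602), neuroectoderm (0.987), trophectoderm (0.904) and germ cells (0.325) were lists of 8 to 14 tested genes. Mesoderm genes had 1 of 10 higher, Eomes (0.35), and 2 lower, Evx1 (-0.92) and T (-0.64), endoderm genes 2 of 9 lower, Sox7 (-1.12) and Lama1 (-0.22), and neuroectoderm genes 1 of 8 higher, Sox1 (0.56), and 1 lower, Sox11 (-0.14). Trophectoderm genes had 2 of 11 higher, among them Eomes, and 2 lower, Gata2 (-0.68) and Tead4 (-0.35), and germ cell genes 1 of 14 lower, Tex19.1 (-0.45). Chromatin silencing genes had 3 of 16 higher and 6 lower (adjusted p = 0.254), with Eed at -0.30 and Atrx at -0.20. Interferon response genes had 3 of 22 higher and 2 lower (adjusted p = 0.746), with Zbp1 at 0.90 and Ddx58 at -0.39. Mitochondrially encoded genes had 1 of 10 higher and 2 lower (adjusted p = 0.325), with mt-Nd6 at -0.22 and mt-Nd2 at -0.15. Replication-dependent histones had none of 17 changed over all genes (edgeR; adjusted p = 0.429 with camera). Feeder fibroblast markers had a median of -0.02 (adjusted p = 0.889), with 2 of 29 higher and 2 lower, among them Ccn2 at -0.37 and Col6a2 at 0.14.

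**Figure D2:**
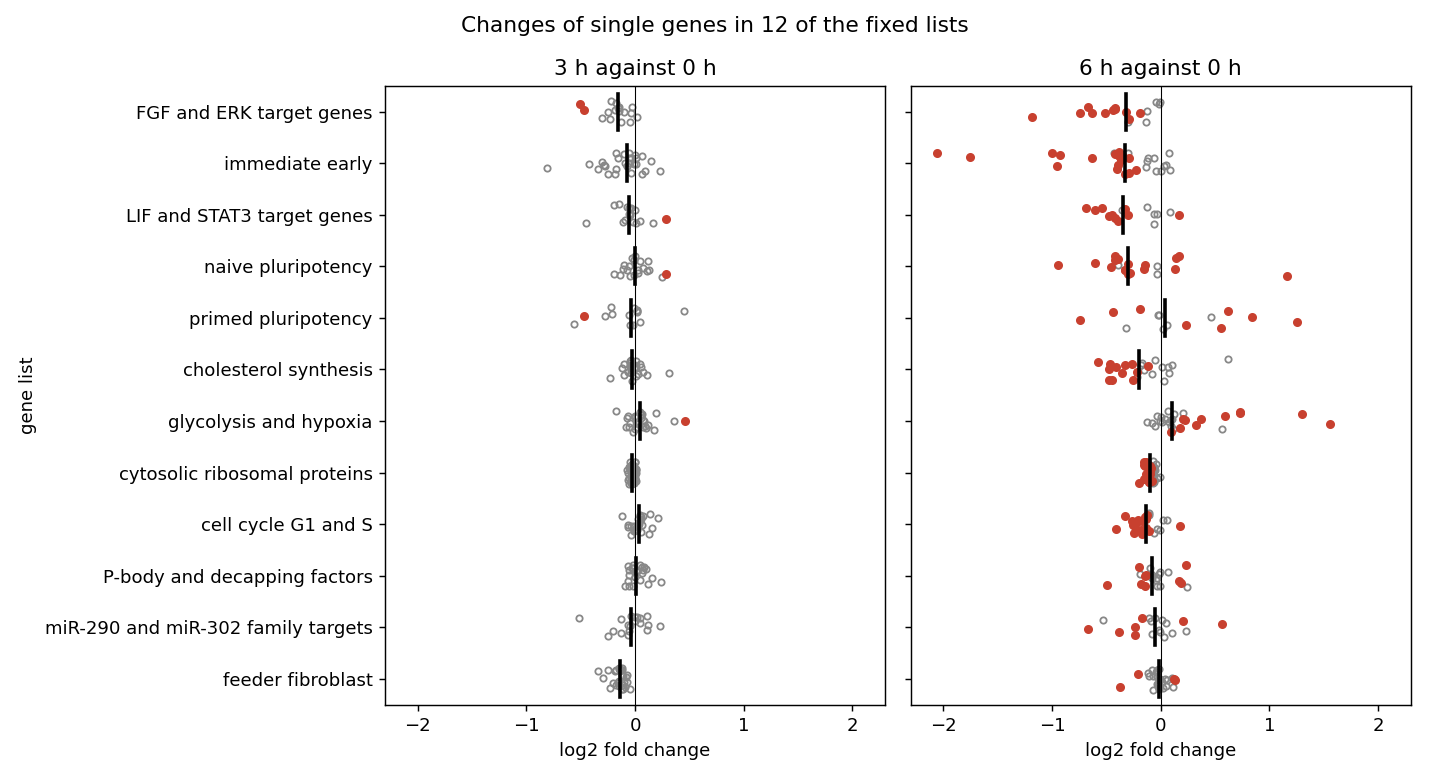
Log2 fold changes (horizontal axis) of the tested members of 12 of the 40 fixed lists (vertical axis) at 3 h and at 6 h against 0 h. Each point is a gene, filled where its adjusted p was under 0.05 and open otherwise, and the black line is the list's median. At 6 h the medians of FGF and ERK target genes and of immediate early genes lay at -0.32 and that of glycolysis and hypoxia at 0.11, and at 3 h few points were filled.

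Among the lists that did not pass camera at 6 h, the counts adjusted over the list alone were those over all genes tested, except in 9 lists. There they were 3 higher and 2 lower for trophectoderm, 3 and 4 for negative regulators of BMP signalling, 3 and 5 for miR-290 and miR-302 targets, 3 and 3 for the microRNA pathway, 4 and 3 for the interferon response, 3 and 1 for aryl hydrocarbon receptor targets, 4 and 3 for Wnt targets, 1 and 3 for mitochondrially encoded genes and 4 and 6 for chromatin silencing. By camera with the preset correlation 17 of the 40 lists passed at 6 h, 2 higher and 15 lower, and none passed with an estimated correlation (lowest unadjusted p = 0.0122). That correlation was 0.61 for glycolysis and hypoxia and 0.41 for naive pluripotency. For mRNAs with AU-rich elements (0.0037) and p53 targets (-0.025) it lay below the preset 0.01. A higher correlation of members thus does not account for the loss of those 2 lists, and what does was not tested. By fry 24 passed, among them 15 of the 17, while glycolysis and hypoxia and CCR4-NOT did not (fry adjusted p = 0.0705 for both). Fry also passed, as lower, the Nodal and activin, chromatin silencing (fry adjusted p = 0.00534 for both) and miR-290 and miR-302 (0.0142) lists. The P-body (0.0458), integrated stress response (0.0475) and Notch (0.0480) lists passed fry as lower too. Passed as higher were the aryl hydrocarbon receptor (0.0153), primed (0.0316) and unfolded protein response (0.0420) lists. Camera passed none of these. Without replicate 2 of 0 h the CCR4-NOT and oxidative phosphorylation lists did not pass (adjusted p = 0.138 and 0.0662), nor did CCR4-NOT without replicate 1 of 6 h (0.137) and heat shock without its replicate 2 (0.0501). Of the 17, the medians of the core pluripotency, CCR4-NOT, oxidative phosphorylation and translation lists lay within the central 95% of matched random lists (35.1%, 22.6%, 13.4% and 32.5% of these were below), and the other 13 lay outside. The random lists hold unrelated genes, so a place outside is weak evidence for lists with high estimated correlations. Of the 23 that did not pass, 6 lay outside, namely germ cell, integrated stress response and Notch lists below and unfolded protein response, aryl hydrocarbon receptor and G2 and M lists above. Among the lists that did not pass, the median and the mean both differed in sign from the test for the mesoderm and Wnt lists. The mean alone did so for the trophectoderm, integrated stress response and mitochondrially encoded lists. The 3515 genes changed at 6 h against 0 h became 2029 with no filter on low counts, and DESeq2 called 1581 of them. Without scaling factors 2128 rose and 1457 fell, in place of 1575 and 1940, a shift of the median of 0.0356 that is smaller than the median of every list that passed as lower at 6 h.

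Many genes differed between 3 h and 6 h. Against 3 h, the largest rises at 6 h were in Cdk5r2 (1.55 ± 0.18), Ankrd37 (2.37-fold), Kif26a (1.22 ± 0.20), Stra6l (1.10 ± 0.23) and Egln3 (1.10 ± 0.07), and the largest falls in Ripply3 (-1.82 ± 0.26), Nr4a3 (-1.72 ± 0.19), Pudp (-1.67 ± 0.24), the collagen gene Col20a1 (-1.54 ± 0.26) and Gpr83 (-1.47 ± 0.16). The number of genes changed at 6 h against 3 h was 3414, 1558 higher and 1856 lower. It was 1712 without replicate 1 of 3 h, 1514 without its replicate 2, 2157 without replicate 1 of 6 h, 1725 with no filter and 1347 with DESeq2. Without scaling factors the split was 2056 higher and 1296 lower, and with a GC offset 1192 and 2492. By camera 18 of the 40 lists passed, and none with an estimated correlation. By fry 25 of the 40 lists passed, and the feeder fibroblast and the glycolysis and hypoxia lists were not among them (fry adjusted p = 0.258 and 0.0990). The number of genes changed at any time was 3598, and it was 2371 without replicate 1 of 6 h, 1626 with no filter and 1551 with DESeq2.

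Of the 8 genes that rose at 3 h, 7 also rose at 6 h, and of the 14 that fell, 12 also fell. Independent lists of these lengths would share 0.800 and 1.72, which leaves out the shared 0 h libraries. In 20 simulated data sets of unchanged groups with shared 0 h libraries, lists of the same lengths, ranked by p, shared 5.9 higher genes on average, from 1 to 8, and 9.7 lower genes, from 5 to 13. The observed overlaps lay within these ranges. The exception among the rises, Tex19.1, fell at 6 h (log2 fold change -0.45 ± 0.06, adjusted p = 2.13e-05). Across the 15748 genes, which are not independent replicates, the changes at 3 h and 6 h correlated at r = 0.361 and rho = 0.328. The same simulations gave r = 0.484 on average, from 0.446 to 0.513. The observed covariance was 0.0285 and the simulated one 0.0210, a difference of 0.00747. With a different 0 h library for each time r was 0.105. In the correlation of the changes at 3 h and 6 h, r was 0.565 without replicate 2 of 0 h. By their size alone, the overlaps may come wholly from the shared 0 h libraries. The comparison of 6 h with 3 h leaves those libraries out. There 7 of the 12 shared falls were called, all lower at 6 h, such as Spry4 (-0.68) and Dido1 (-0.52). Of the 7 shared rises 4 were called, Egln3 and Elf3 higher and Klf4 and Tnrc6a lower. For the 7 falls, Egln3 and Elf3 this argues against the 0 h libraries as the only source of their 6 h calls. Their 3 h calls were not tested in this way. The correlation lay below the simulated range and the covariance above its highest value of 0.0222. The simulations held no changed genes, and changes at 6 h alone lower r, so the low r does not count against shared changes. With a different 0 h library for each time the covariance was 0.00855. With 2 libraries at 0 h these values do not settle whether the changes are shared.

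P-body mRNAs are known to be AU-rich, which makes base composition a property of interest. Across 13511 genes the log2 fold change at 6 h rose with the GC content of the coding sequence at rho = 0.0770 and of the 3' UTR at rho = 0.0881. For the coding sequence, the difference between replicate libraries gave rho = -0.0681 at 0 h, -0.179 at 3 h and -0.0997 at 6 h, and the largest of these exceeded the 6 h value in size. For the 3' UTR these values were -0.0291, -0.155 and -0.0685. At 3 h the coding value was rho = -0.0668. By terciles of expression the 6 h coding values were 0.101, 0.0115 and -0.0190 from the lowest to the highest, and the 3' UTR values 0.122, 0.0357 and 0.0370. By terciles of the length of coding sequence and 3' UTR together they were 0.0799, 0.0864 and 0.0718 for the coding sequence and 0.0851, 0.0963 and 0.0872 for the 3' UTR.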

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

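The comparison of 6 h with 3 h and its DESeq2 and left-out-library alternatives were planned, whereas its list tests, the thinning to equal depth and the tests of explanations were chosen after the result was seen. The change between the times was tested directly, and 3414 genes differed between 6 h and 3 h.

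Klf4, which was higher than at 0 h at both times, was lower at 6 h than at 3 h (log2 fold change -0.11, adjusted p = 0.0395). Tnrc6a did the same (-0.14, adjusted p = 0.0165). Tex19.1, expressed in pluripotent and germ cells, was higher at 3 h and lower at 6 h than at 0 h, with a difference of -0.73 between the times (adjusted p = 1.57e-07). The transcription factor gene Rreb1 was lower at 3 h and higher at 6 h than at 3 h (0.38), and Zfp532 likewise (0.17), both chosen after their values were seen. The median of the feeder fibroblast list was 0.13 higher at 6 h than at 3 h (camera adjusted p = 3.00e-06, and adjusted p = 0.396 with an estimated correlation). The median of the CCR4-NOT and deadenylation list was lower by that measure, at -0.13 (adjusted p = 0.000128, and adjusted p = 0.332 with an estimated correlation).

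The breadth of the change at 6 h was weighed against 3 explanations. Lower depth of the 6 h libraries was argued against, since 3277 genes were still called with counts thinned to equal depth. A different share of feeder cells was argued against by the median of the feeder list, -0.018, when changed genes moved by a median size of 0.287. The SE of the list was 0.0193, but it was taken over genes with an estimated correlation of 0.61, not over libraries. By library the mean log2 CPM of the list was 8.90 and 8.80 at 0 h and 8.91 and 8.75 at 6 h. A smaller difference in feeder share is left open. The treatment medium or 5-Ph-IAA itself and not the loss of DDX6 cannot be told apart. The libraries used here held 0 groups of untreated wells kept for 3 or 6 h and no treated ES cells without the degron. Any renewal of the MEK inhibitor with the medium could then have lowered FGF and ERK target genes, a hypothesis that these libraries leave untested, as they do the loss of DDX6 as a cause.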

How the results depend on the processing

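The settings with library sizes only, a GC offset, thinning, without 5 genes that collect ribosomal RNA reads and Ldb1, and the list tests for 6 h against 3 h were chosen after the result was seen, and the others were planned. With no filter on low counts the numbers of changed genes were 0 at 3 h, 2029 at 6 h, 1725 for 6 h against 3 h and 1626 for genes changed at any time, and with DESeq2 12, 1581, 1347 and 1551. More genes enter the adjustment without the filter, and the cause of the DESeq2 difference was not tested. At 3 h the count was also 53 with the feeder-marker mean as a covariate, 74 with only the 4 libraries compared and 35 without the rRNA-linked genes and Ldb1, and the cause was not tested. Leaving out each library gave 4 to 249 genes at 3 h, 2488 to 3092 at 6 h, 1514 to 3706 for 6 h against 3 h and 2371 to 3752 at any time. A lone library was assumed to vary like the others. Of the 3515 genes at 6 h, 1538 were called in all 6 of these fits and 3512 kept their sign in them. The lists past the threshold at 3 h were 6 to 14 without a library, and 0 with an estimated correlation and 0 by fry. At 6 h and for 6 h against 3 h they were 0 and 0 with an estimated correlation, and 24 and 25 by fry. The log2 fold change of Ddx6, 6 h against 0 h, turned to 0.0012 with library sizes only and lay between -0.082 and 0.021 without a library. That of Dcp1a, 3 h against 0 h, lay between -0.047 and 0.0059. The correlation of the changes at 3 h and 6 h ran from 0.3002 to 0.565 without a library, while the simulations used 2 control libraries. The relation with GC content was -0.0668 at 3 h in place of 6 h, and the cause was not tested. Of the named genes called, 3 of 16 at 3 h, 100 of 118 at 6 h and 9 of 10 for 6 h against 3 h were called in every fit without a library, as were 4 of the 10 lists at 3 h and 14 of the 17 at 6 h. In counts simulated at this depth with 2 libraries per time, planted changes of the smallest size were found in 70% of genes at 3 h and 64% at 6 h, and other depths were not simulated.

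With the replicate number as a replicate block the count of genes changed at 3 h against 0 h was 242, of genes changed at 6 h against 0 h 4227, of genes changed at 6 h against 3 h 4186 and of genes changed at any time 4709, and 14 lists passed at 3 h. Across all genes, deviations of libraries with the same number correlated little (0.0372, 0.0401 and -0.0212). The labels do not say that the numbers pair libraries, so the main fit held no block. Replicate 2 minus replicate 1 had a negative rho with coding GC content at each time (-0.0681, -0.179 and -0.0997). A shared replicate effect is therefore not excluded.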

Other observations

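All gene families and tests below were chosen after the result was seen. Of 19 gene families examined at 6 h against 0 h, Srsf splicing factors, which bind exonic enhancers, were lower, with 7 of 11 lower and none higher (median -0.15, camera adjusted p = 0.000111, and adjusted p = 0.534 with an estimated correlation). Srsf5 fell by 0.35, Srsf2 by 0.24 and Srsf6 by 0.23 on the log2 scale. At 3 h the median of this family was 0.06 with no member called over all genes (adjusted p = 0.00926, and adjusted p = 0.760 with an estimated correlation). Snhg genes, which host small nucleolar RNAs in their introns, had 8 of 14 lower and 1 higher (median -0.27, adjusted p = 0.00131, and adjusted p = 0.534 with an estimated correlation). Snhg3 fell by 0.38, Snhg12 by 0.38 and Snhg1 by 0.29, and Snhg11 rose by 0.38. Genes with a Kif symbol, mostly kinesins, had 11 of 38 higher and 2 lower (median 0.07, adjusted p = 0.0144, and adjusted p = 0.534 with an estimated correlation), with Kif5c at 0.72, Kif26b at 0.56 and Kif23 at 0.42 higher and Kifc5b at -0.22 and Kifc1 at -0.20 lower. They include Kifap3 and Kif1bp, which do not encode kinesins and were not called changed. Of 10000 random lists matched on expression, 1.23% had a median below that of the Srsf family, 0% below that of the Snhg genes and 99.9% below that of the Kif genes. Genes picked by a symbol of Klf or Sp and a number had 1 of 26 higher and 9 lower (median -0.04, adjusted p = 0.0336, and adjusted p = 0.599 with an estimated correlation), and 34.8% of matched lists had a lower median. They include Sp100 and Sp3os, which are not Klf or Sp factors and were not called changed. Hox genes had 1 of 34 higher and 6 lower (median -0.16, adjusted p = 0.375), and 0.08% of matched lists had a lower median. C2H2 zinc finger genes had 40 of 413 higher and 77 lower (adjusted p = 0.270).

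Ldb1, a cofactor of LIM-domain proteins (chromosome 19, 46031570 to 46045214), was about 10 times as high in replicate 2 of 6 h, with 36146 counts against 3046 to 4424 in the other libraries. Its log2 fold change at 6 h was 2.43 ± 0.57 (edgeR adjusted p = 0.00526), and it rests on that library. Reads from the genomic neighbourhood were argued against, since 4 tested genes within 100 kb had a median log2 ratio of -0.13. Cells of another type or another library that differ in many genes, mixed into this one, were also argued against. In that test 0 other genes stood 4 times above their highest value elsewhere. It could not see a mixed-in source that differed mainly in Ldb1. No biological explanation was tested, and a jump in a single library may be technical.

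CT010467.1 and Lars2 were called higher at 6 h and belong to 5 genes known to collect ribosomal RNA reads. CT010467.1 measured 1384 and 4459 CPM at 0 h, 5789 and 8058 at 3 h, and 10913 and 5197 at 6 h, and Lars2 153 and 374, 528 and 721, and 940 and 376. The log2 ratio of the pair had an SD of 0.198 over the 6 libraries, 0.193 times the SD of CT010467.1 (1.02), which is consistent with ribosomal RNA left over in differing amounts. A response to the treatment cannot be told apart, because the lowest 6 h library of CT010467.1 lay above the highest 0 h library by 0.221 on the log2 scale while the SD within 0 h was 1.19, and 2 libraries per time are too few for an exact test.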
